A study of Mus musculus with 6 samples.

How the data were processed

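RNA from 6 samples of mouse prostate cancer cells that lack Trp53 and Rb1 was measured on Affymetrix whole-transcript mouse gene arrays, 3 for empty-vector (EV) cells and 3 for PIM1-transduced cells. Per the labels' protocols, cells grew in a medium with charcoal-stripped serum and growth supplements, RNA was extracted with Trizol and RNeasy kits, and labelled cDNA was prepared from total RNA with the GeneChip WT PLUS kit. The values deposited by the authors are 1 number per probe set and array, and they were taken as log2 signals. Their range, from 0.34 to 13.0, and the tool named with them are those of log2 summaries, but the log base is not given in the sources used here. Affymetrix Expression Console is named in the submitters' processing notes, without a version. The background correction, the summarization of probes and the normalization between arrays are not given in the sources used here. The deposited log2 values had no missing entries and close but unequal distributions, with medians of 3.50 ± 0.014 (SD, n = 3) for EV and 3.40 ± 0.016 for PIM1. The authors' normalization was therefore kept and nothing was scaled again for the reported values. Each group has 3 arrays, and their number limits the precision. No detection call was used, so low signals hold an unknown share of background.

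Groups were taken from the sample titles. Gene names came from the platform annotation supplied with the values, checked through Entrez identifiers against the mouse RefSeq annotation of assembly GRCm38.p6, which was used only for names and gene order. Of 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none. Of the named probe sets 23328 matched RefSeq by identifier, 193 did not, and 0 symbols needed updating. For 1082 genes with more than 1 probe set the one with the highest mean over the 6 arrays was used, which left 22180 genes. Probe sets with several or no symbols were left out of the gene tests, and list members without a probe set of their own were not analysed here, Trp53 among the named genes.

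The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05, and, for the 2-fold count, a log2 difference of at least 1. The 32 gene lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. For each list the members that passed were counted over all genes tested and adjusted over the list alone. The tests, the lists and the rule for named genes were fixed before the data were examined. The rule takes Pim1, Pim2, Pim3, Trp53 and Rb1, then the 12 largest rises and 12 largest falls among genes with adjusted p under 0.05 and no overlap between the groups, leaving out predicted loci and large repeated families, and for each list the 2 to 4 members with the smallest p. Tnf, Taldo1, Inhba, Skil and Fap are named as well because they moved against their lists, and they were chosen after their values were seen. The gene families of the closing section, and Lum, Thy1, Col1a1, Col3a1, Krt8 and Epcam there, were also chosen after their values were seen.

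The scripts were tested on simulated data with the mean and spread of each of the 22180 genes. Of 67 genes changed by 0.5 on the log2 scale 16.4% were recovered, of 67 changed by 1 71.6% and of 66 changed by 2 97.0%. Among 124 calls 1 was false. The list test called the 1 shifted list of 20 genes and 0 of the others. Few of the 22180 genes were changed there, whereas 5995 were called on the real arrays, so this recovery need not hold for them. The simulation was set by the mean and spread of single genes, so it does not check the preset correlation of the list test. Splits of the real arrays that mixed the groups called 6 to 10 lists each, with 0 genes called. Each mixed split keeps part of the real group difference and puts the rest into the spread within its sides. Its counts are therefore no measure of false calls. With an estimated correlation 5 of the 11 list calls held.

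Alternatives were a trended and robust variance, quantile normalization, centring each array on its median, testing only the brighter 11090 genes, averaging the probe sets of a gene, testing all probe sets, the replicate number as a block, leaving out each array in turn, and camera with an estimated correlation or fry for the lists. Cyclic loess, and the 2-fold count over all probe sets, were added after seeing the data. Array similarity was described by Pearson correlation and principal components over the genes tested. In the closing section, gene positions entered only as the order of genes along chromosomes, and 10000 rotations of that order and 100000 permutations gave the reference values for chromosomes.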

Results

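Gene expression was measured in prostate epithelial cancer cells from mice in which Trp53 and Rb1 had been deleted in the prostate. PIM1 is a serine/threonine kinase that is often highly expressed in haematological and prostate cancers. The cells carried either a lentivirus for PIM1 (PIM1 cells, 3 arrays) or the same kind of virus without an insert (EV cells, 3 arrays). The comparison of PIM1 with EV asked which genes differed in expression between PIM1-expressing and control cells of this Trp53 and Rb1 double-knockout background. Values are log2 signals on a whole-transcript mouse array, given as mean ± SD with n = 3 arrays per group, and differences are PIM1 minus EV. The labels name no separate cultures or transductions for the arrays of a group, so the p-values measure only the spread between these samples, which may be technical.

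Pim1 signal was 5.26, 6.25 and 5.23 on the 3 EV arrays and 7.11, 6.89 and 6.97 on the 3 PIM1 arrays. The Pim1 difference was 1.41 on the log2 scale (standard error 0.255, adjusted p = 0.00456), a 2.65-fold rise, and all 3 PIM1 arrays lay above all 3 EV arrays. A dimmer second probe set of Pim1 differed by 0.68 (adjusted p = 0.0933 over all probe sets) and was not called. The labels give neither the species of the PIM1 insert nor the position of the probes on it, so the Pim1 signal may not measure the introduced sequence. The related kinase genes Pim2 and Pim3 were not called. Pim2 read 4.61, 4.94 and 5.21 on the EV arrays and 5.20, 5.39 and 5.24 on the PIM1 arrays (difference 0.36, adjusted p = 0.132). Without EV replicate 3 the Pim2 difference was 0.50 and passed (adjusted p = 0.0379). Pim3 read 5.68, 5.34 and 6.01 against 5.91, 5.96 and 5.88 (difference 0.24, adjusted p = 0.329). Rb1, the retinoblastoma gene targeted in these mice, read 4.49, 4.06 and 4.87 on the EV arrays and 4.80, 4.50 and 5.26 on the PIM1 arrays, a difference of 0.38 (adjusted p = 0.293). A dimmer second probe set of Rb1 differed by -0.35 (adjusted p = 0.295 over all probe sets), the opposite sign, and was not called. The Rb1 levels compare 2 groups that share the knockout, and they check nothing about it. Trp53 was not analysed here.

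The largest difference between PIM1 and EV cells was that of Saa3. This gene of an acute-phase serum amyloid A protein rose from 3.04 ± 0.12 to 12.50 ± 0.03, a 704-fold difference (adjusted p = 3.37e-09). Steap4, a metalloreductase of the cell surface, rose by 8.04, and Lcn2, a lipocalin that binds iron-carrying siderophores, rose by 7.52 on the log2 scale. On the other side Gpr149, an orphan G protein-coupled receptor, fell by 5.32 from 9.83 ± 0.10 to 4.51 ± 0.25. Krt18, a keratin of simple and luminal epithelium, fell by 4.24 from 9.14 ± 0.06 to 4.90 ± 0.12, an 18.9-fold difference (adjusted p = 1.86e-07).

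The 12 largest rises held 9 further genes. Lbp, which binds bacterial lipopolysaccharide, rose by 6.54 (93.4-fold). The chemokine genes Cxcl5 and Cxcl15, whose products attract neutrophils, rose by 5.78 and 5.73, and Ptx3, a soluble pattern-recognition protein, rose by 5.31. Ch25h, which makes an oxysterol from cholesterol, rose by 5.40. Dcn, the matrix proteoglycan decorin, rose by 5.48 from 4.86 ± 0.09 to 10.33 ± 0.16. The remaining rises were those of Rasl11a, a small GTPase (5.49), Lgi2, a secreted leucine-rich repeat protein (5.29), and Chl1, a neural cell adhesion molecule (5.20). The other large falls included Nes, the intermediate filament protein nestin (-4.23), Sema3e, a secreted guidance cue (-3.81), and the actin regulator Fmnl1 (-3.35). Alcam, an immunoglobulin-type adhesion molecule, fell by 3.32, H60b, a ligand of an activating receptor of natural killer cells, by 3.16, and Pbp2 by 3.12. Trpc6, a cation channel, fell by 3.08, Npr3, the clearance receptor for natriuretic peptides, by 3.07, Tnnt2, cardiac troponin T, by 3.06, and Epha3, an ephrin receptor, by 2.93. Adjusted p among these 24 genes was between 3.37e-09 for Saa3 and 7.75e-05 for Fmnl1. No detection call was used, so folds against low EV signals such as that of Saa3 rest in part on background.

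Of 22180 genes tested, 5995 (27.0%) passed adjusted p under 0.05, 3575 higher and 2420 lower in PIM1. Thus 59.6% of the changed genes were higher, and this share was 73.5% after each array was centred on its median. A change of at least 2-fold was called for 1388 genes, 1010 higher and 378 lower. The arrays of the groups did not overlap for 9581 genes (43.2%), where chance gives 10%. Arrays of 1 group correlated at 0.990 to 0.991 among EV and 0.994 to 0.997 among PIM1, and arrays of different groups at 0.963 to 0.967. The first principal component held 76.5% of the variance and separated the groups. The values spread wider on the PIM1 arrays, with an interquartile range of 3.51 ± 0.039 against 3.24 ± 0.018 on the EV arrays.

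**Figure D1:**
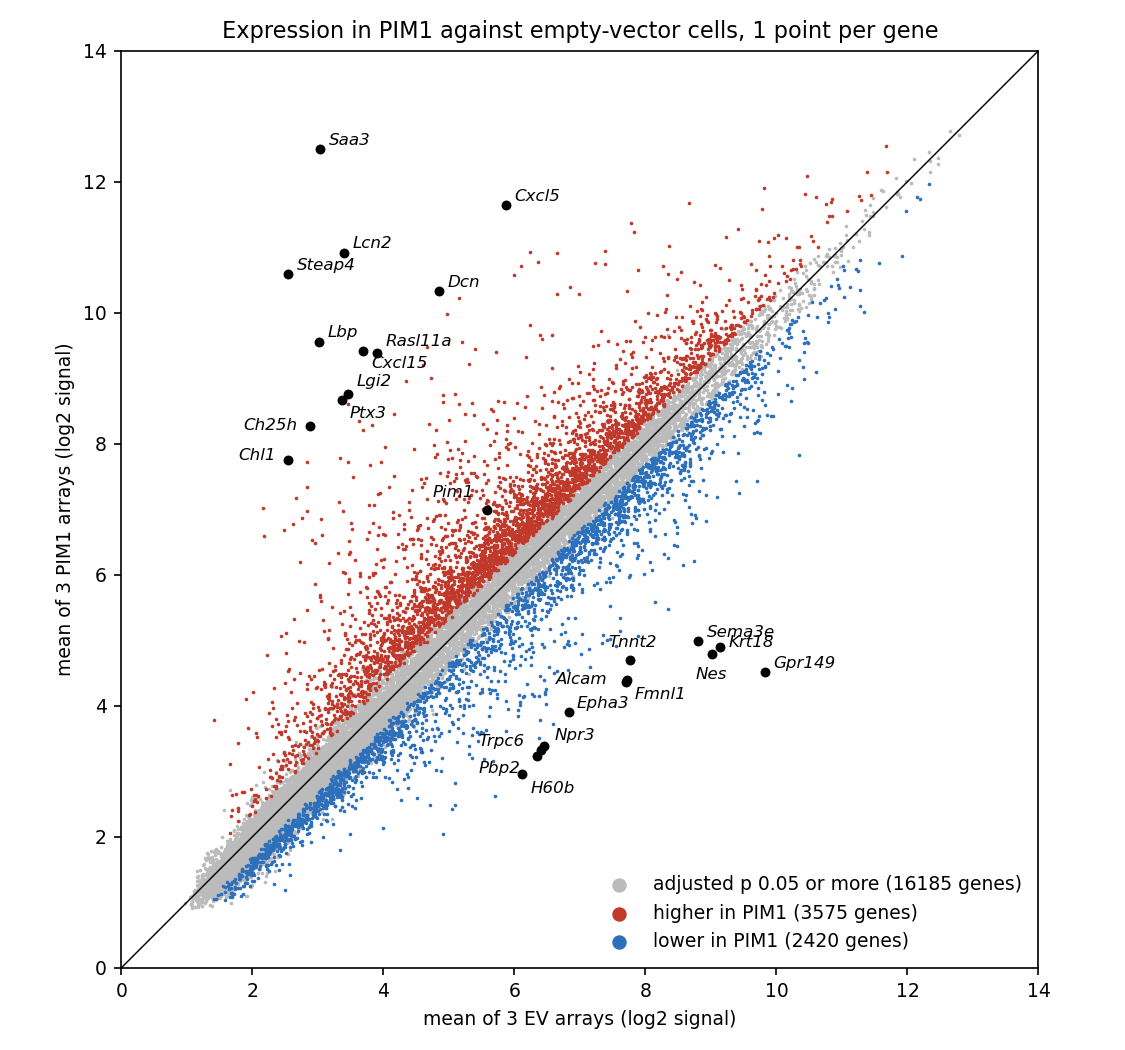
Mean log2 signal of the 3 EV arrays (x axis) against the mean of the 3 PIM1 arrays (y axis), 1 point per gene, with 3575 genes called higher in red, 2420 called lower in blue and the others in grey; the line marks equal signal. Saa3, at 3.04 in EV and 12.50 in PIM1, lies farthest above the line, and Gpr149, at 9.83 and 4.51, farthest below it among the labelled genes.

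Inflammatory genes formed the list with the largest shift. Of 25 measured genes for inflammatory cytokines and chemokines, 19 rose and 1 fell over all genes tested (21 and 1 adjusted over the list alone), with a median difference of 2.24 and a camera adjusted p of 1.05e-16. Besides Saa3, Cxcl15 and Cxcl5, the T cell chemokine gene Ccl5 rose by 4.62, from 4.35 ± 0.12 to 8.96 ± 0.08. Tnf, the tumour necrosis factor gene, was the member that fell, by 0.58 from 3.485 ± 0.256 to 2.908 ± 0.292, a low signal (adjusted p = 0.0476). Tnf did not pass after quantile normalization, median centring or cyclic loess (adjusted p = 0.0928, 0.0768 and 0.0805) or without EV replicate 1 or 2 (0.121 and 0.0673) or PIM1 replicate 2 or 3 (0.0910 and 0.134). NF-kappaB feedback genes rose in 13 of 17 cases with none falling (14 and 1 adjusted over the list alone), and their median difference was 1.42 (camera adjusted p = 9.50e-10). This call was lost at adjusted p = 0.0539 with an estimated correlation. Vcam1, an endothelial and stromal adhesion molecule, rose by 3.54, and the pathway inhibitors Tnip1 and Nfkbie rose by 2.02 and 2.20. Of 17 STAT3 and STAT5 target genes, 11 rose and 0 fell (12 and 0 adjusted over the list alone; median 1.32, camera adjusted p = 6.03e-10). Lcn2 led this list. Cebpb, a transcription factor of the acute-phase response, rose by 2.29, Osmr, the oncostatin M receptor, by 2.25, and Il4ra, the interleukin-4 receptor chain, by 2.10. In the same PIM1 arrays the 12 fibroblast markers had a median difference of 1.10.

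Genes of the interferon response and of antigen presentation were also higher in PIM1 cells. Of 24 measured interferon response genes, 18 rose and 0 fell (18 and 0 adjusted over the list alone), with a median difference of 1.20 and a camera adjusted p of 1.36e-10. This call was lost at adjusted p = 0.0539 with an estimated correlation. Oasl2, an oligoadenylate synthetase-like protein, rose by 2.65, the chemokine gene Cxcl10 by 2.19, Usp18, a protease that removes ISG15 from proteins, by 2.66, and the transcription factor gene Stat2 by 1.80. Among 14 MHC class I antigen presentation genes, 11 rose and 0 fell (13 and 0 adjusted over the list alone; median 1.38, camera adjusted p = 5.71e-09). H2-K1, a class I heavy chain, rose by 3.69 from 5.72 ± 0.38 to 9.40 ± 0.03. The immunoproteasome subunit gene Psmb8 rose by 2.19, the class I light chain gene B2m by 1.63 and the peptide-loading factor gene Tapbp by 1.25. Probe sets of closely related genes, such as the class I heavy chains, can share signal. The fibroblast marker median of 1.10 applies to these arrays as well.

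Hypoxia-inducible and glycolysis genes rose in 19 of 23 cases, with 0 falling (19 and 0 adjusted over the list alone), a median difference of 0.63 and a camera adjusted p of 2.39e-10. Adm, which encodes the vasodilator peptide adrenomedullin, rose by 4.82 from 4.66 ± 0.04 to 9.48 ± 0.13. Car9, a carbonic anhydrase of the cell surface, rose by 2.30, the oxygen sensor gene Egln3 by 1.75 and Ndrg1 by 1.27. Of 17 NRF2-linked antioxidant genes, 11 rose and 1 fell (11 and 2 adjusted over the list alone; median 0.69, camera adjusted p = 3.78e-05), and the call was lost at adjusted p = 0.0644 with an estimated correlation. Sod2, the mitochondrial superoxide dismutase, rose by 2.66, Gstm1, a glutathione transferase, by 1.41 and Pgd, an enzyme of the pentose phosphate pathway, by 1.05, whereas Taldo1, of the same pathway, fell by 0.61. Endoplasmic reticulum chaperone genes rose in 10 of 16 cases and fell in 0 (10 and 0 adjusted over the list alone; median 0.44, camera adjusted p = 1.56e-04). Their call was lost at adjusted p = 0.0539 with an estimated correlation. The folding factor genes Pdia6, Sdf2l1 and Creld2 rose by 0.93, 1.01 and 0.92. Beside these 3 lists stands the same median difference of 1.10 for fibroblast markers.

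Of 12 fibroblast markers, 8 rose and 1 fell over all genes tested (8 and 1 adjusted over the list alone), with a median difference of 1.10 and a camera adjusted p of 5.25e-06. Besides Dcn, Pdgfra, a platelet-derived growth factor receptor, rose by 4.70 from 6.23 ± 0.28 to 10.93 ± 0.11. Fbln1 and Dpt, which encode matrix proteins, rose by 1.94 and 2.58. Fap, a surface protease of activated fibroblasts, fell by 0.47 from 2.18 ± 0.04 to 1.72 ± 0.12, and it did not pass after quantile normalization or cyclic loess (adjusted p = 0.0541 and 0.0546) or without PIM1 replicate 1 or 2 (0.0516 and 0.0553). Matrix and protease genes rose in 13 of 23 cases and fell in 5 (13 and 6 adjusted over the list alone; median 0.61, camera adjusted p = 0.00809). Their call was lost at adjusted p = 0.0932 with an estimated correlation, and at 0.295 when only the brighter 11090 genes were tested. The collagenase gene Mmp13 rose by 4.61, the stromelysin gene Mmp3 by 3.40 and the protease inhibitor gene Timp3 by 1.46, whereas Plau, the urokinase plasminogen activator, fell by 2.86. Of 17 TGF-beta and BMP target genes, 13 rose and 3 fell (13 and 3 adjusted over the list alone; median 1.00, camera adjusted p = 8.03e-05), and the call was lost at adjusted p = 0.0539 with an estimated correlation. Ltbp2, a latent TGF-beta binding protein, rose by 2.23, and the ligand gene Bmp4 and the BMP signalling inhibitor gene Smad6 each rose by about 1.64. The members that fell were Pmepa1, a feedback inhibitor of TGF-beta signalling (-2.48), the activin subunit gene Inhba (-1.82) and the repressor gene Skil (-1.54).

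Mesenchymal genes moved both ways and the list was not called (8 of 18 rose and 4 fell, 9 and 4 adjusted over the list alone; median 0.25, camera adjusted p = 0.155). The gelatinase gene Mmp2 rose by 3.30 and the cadherin gene Cdh11 by 2.09, whereas Cdh2, which encodes N-cadherin, fell by 1.49. YAP and TEAD target genes were likewise not called (9 of 17 rose and 4 fell, 10 and 4 adjusted over the list alone; median 0.35, camera adjusted p = 0.274). Arhgef17 rose by 3.01 and Amotl2 by 0.94, whereas the junction-associated protein gene Ajuba fell by 1.31.

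Luminal prostate markers, Krt18 among them, were not called as a list. Of 15 measured, 2 rose and 4 fell (2 and 5 adjusted over the list alone; median -0.25, camera adjusted p = 0.103). Cd24a, a glycosylphosphatidylinositol-anchored surface protein, rose by 1.65. Of 16 basal epithelial markers, 0 rose and 3 fell (0 and 3 adjusted over the list alone; median -0.13, camera adjusted p = 0.0972), and this list passed without EV replicate 2 (adjusted p = 0.0320). When only the brighter 11090 genes were tested, the basal median was -1.29 and the list passed (adjusted p = 0.0270). That median is the difference of Cdh3 alone. The lower quartile of all 16 basal markers was -0.40, so few of them can have passed the brightness filter. The basal markers that fell over all genes tested were the laminin receptor subunit gene Itga6 (-2.10), the P-cadherin gene Cdh3 (-1.29) and the laminin chain gene Lamb3 (-1.03). Of 24 epithelial junction genes, 1 rose and 4 fell (1 and 4 adjusted over the list alone; median -0.11, camera adjusted p = 0.264). Among the brighter genes alone the junction median was -0.48 and the list passed (adjusted p = 0.0213), whereas after quantile normalization the median was 0.03 (adjusted p = 0.693). The lower quartile of all 24 junction genes was -0.29, so few of them can have passed the brightness filter. Cdh1, which encodes E-cadherin, fell by 0.94 from 5.21 ± 0.27 to 4.27 ± 0.05. The epithelial transcription factor gene Elf3 rose by 0.99 at a low signal, from 2.54 ± 0.28 to 3.53 ± 0.19. Of 19 neuroendocrine markers, 1 rose and 3 fell (1 and 2 adjusted over the list alone; median 0.0044, camera adjusted p = 0.796). The transcription factor gene Foxa2 rose by 0.81, and Mycn fell by 0.59 at a low signal, from 3.75 ± 0.14 to 3.16 ± 0.21. Without PIM1 replicate 2 or 3 the Mycn difference did not pass (adjusted p = 0.0607 and 0.0542). Junction, basal and neuroendocrine members had median EV levels of 3.135, 2.92 and 3.01, below the median of the EV arrays (3.50). Members at such low signals have little room to fall, so the missing calls do not show that these markers were kept.

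Macrophage and leukocyte, endothelial and smooth muscle markers, which other cells in a culture could bring, were not called as lists. Of 13 macrophage and leukocyte markers, 1 rose and 2 fell (1 and 2 adjusted over the list alone; median -0.24, camera adjusted p = 0.169). The lipopolysaccharide co-receptor gene Cd14 rose by 2.20 and the macrophage growth factor receptor gene Csf1r fell by 1.35. None of 12 endothelial markers passed (0 rose and 0 fell adjusted over the list alone; median -0.03, camera adjusted p = 0.767). Cldn5 and Emcn had the smallest p among them, with differences of -0.23 and -0.34, and Emcn passed without EV replicate 3 (-0.52, adjusted p = 0.0128). Emcn lay at a low signal, 2.42 in EV and 2.08 in PIM1. The endothelial members had a median EV level of 2.94, below the median of the EV arrays (3.50). Of 10 smooth muscle markers, 2 rose and 3 fell (2 and 3 adjusted over the list alone; median -0.22, camera adjusted p = 0.274). The actin-binding protein gene Tagln fell by 1.56 and the enteric actin gene Actg2 by 1.19, whereas the calponin gene Cnn1 rose by 0.62.

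Mitotic genes fell in 6 of 21 cases with 0 rising (6 fell and 1 rose adjusted over the list alone; median -0.17), and the list was not called (camera adjusted p = 0.0850). The spindle motor gene Kif11 fell by 1.02, the kinetochore motor gene Cenpe by 0.84 and the topoisomerase gene Top2a by 0.69. After quantile normalization the mitotic list passed, with a median of -0.24 (adjusted p = 0.00203), as it did after cyclic loess (adjusted p = 0.00240) and among the brighter genes alone (median -0.17, adjusted p = 0.0202). Of 20 DNA replication genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone; median -0.01, camera adjusted p = 0.785). The cell cycle genes E2f1 and Ccne1 rose by 0.69 and 0.74, and the polymerase gene Pola1 fell by 0.81. Replication-dependent histone genes had 1 rise and 0 falls among 5 (2 and 0 adjusted over the list alone; median 0.41, camera adjusted p = 0.0708). H1f2, a linker histone, rose by 1.08, and H2bc21 differed by 0.48 (adjusted p = 0.0656, and 0.0355 without EV replicate 2, 0.0373 after median centring and 0.0332 among the brighter genes alone). The histone list passed without EV replicate 2 (adjusted p = 0.0440) or without PIM1 replicate 3 (adjusted p = 0.0169). Of 22 MYC-linked ribosome biogenesis and growth genes, 2 rose and 5 fell (3 and 5 adjusted over the list alone; median -0.06, camera adjusted p = 0.274). The nucleolar protein genes Npm1, Ncl and Nop58 fell by 1.32, 0.87 and 0.71. After quantile normalization the MYC-linked list passed, with a median of -0.15 (adjusted p = 0.0257), as it did after cyclic loess (adjusted p = 0.0319).

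Respiratory chain, cholesterol synthesis, fatty acid synthesis and amino acid stress lists were not called. Mitochondrial respiratory chain genes had 2 rises and 5 falls among 22 (2 and 5 adjusted over the list alone; median 0.0087, camera adjusted p = 0.558), with Cox4i1, a cytochrome c oxidase subunit, falling by 1.25 and the complex I subunit gene Ndufa9 by 0.70. Of 16 cholesterol synthesis genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone; median -0.0044, camera adjusted p = 0.767). The kinase gene Pmvk fell by 0.55 and Nsdhl rose by 0.38, and Nsdhl did not pass without PIM1 replicate 2 (adjusted p = 0.0684). Fatty acid synthesis genes had 4 rises and 2 falls among 13 (4 and 2 adjusted over the list alone; median -0.03, camera adjusted p = 0.770). Acss2, an acetyl-CoA synthetase, rose by 1.19 and the desaturase gene Scd1 by 0.49. Among 22 ATF4-linked amino acid stress genes, 7 rose and 5 fell (7 and 6 adjusted over the list alone; median 0.11, camera adjusted p = 0.767). Slc7a5, a large neutral amino acid transporter, fell by 1.52, and Cth, which makes cysteine from cystathionine, rose by 1.62.

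Lists of p53 targets, apoptosis regulators, ERK-responsive genes and WNT and NOTCH targets each held changes in both directions without a call. Of 17 p53 target genes, 6 rose and 4 fell (7 and 4 adjusted over the list alone; median 0.0051, camera adjusted p = 0.591). The death receptor gene Fas rose by 3.83 and the stress gene Sesn1 by 1.42, whereas the membrane protein gene Perp fell by 2.15 and the cyclin-dependent kinase inhibitor gene Cdkn1a by 1.44. Both groups share the deletion of Trp53, so this list is not a measure of p53 activity here. BCL2 family and apoptosis regulators had 3 rises and 2 falls among 18 (5 and 3 adjusted over the list alone; median -0.08, camera adjusted p = 0.854). Bid, a pro-apoptotic member, rose by 0.56 and Xiap, a caspase inhibitor, fell by 0.52. Of 18 ERK-responsive genes, 7 rose and 5 fell (7 and 5 adjusted over the list alone; median 0.00094, camera adjusted p = 0.785). The feedback inhibitor genes Spry1 and Dusp5 fell by 1.57 and 1.12, the growth factor gene Ereg fell by 1.45 and the transcription factor gene Etv1 rose by 1.17. WNT and NOTCH target genes had 3 rises and 8 falls among 19 (3 and 10 adjusted over the list alone; median -0.35), at a camera adjusted p of 0.0504. Hes1, a NOTCH target repressor, fell by 2.11, its relative Hey1 by 0.73 and the WNT feedback gene Axin2 by 0.61. After median centring this list passed with a median of -0.25 (adjusted p = 0.0276), as it did after quantile normalization, after cyclic loess and with averaged probe sets (adjusted p = 0.0279, 0.0229 and 0.0474). It also passed without EV replicate 1, PIM1 replicate 1 or PIM1 replicate 3 (adjusted p = 0.0435, 0.0411 and 0.0345).

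**Figure D2:**
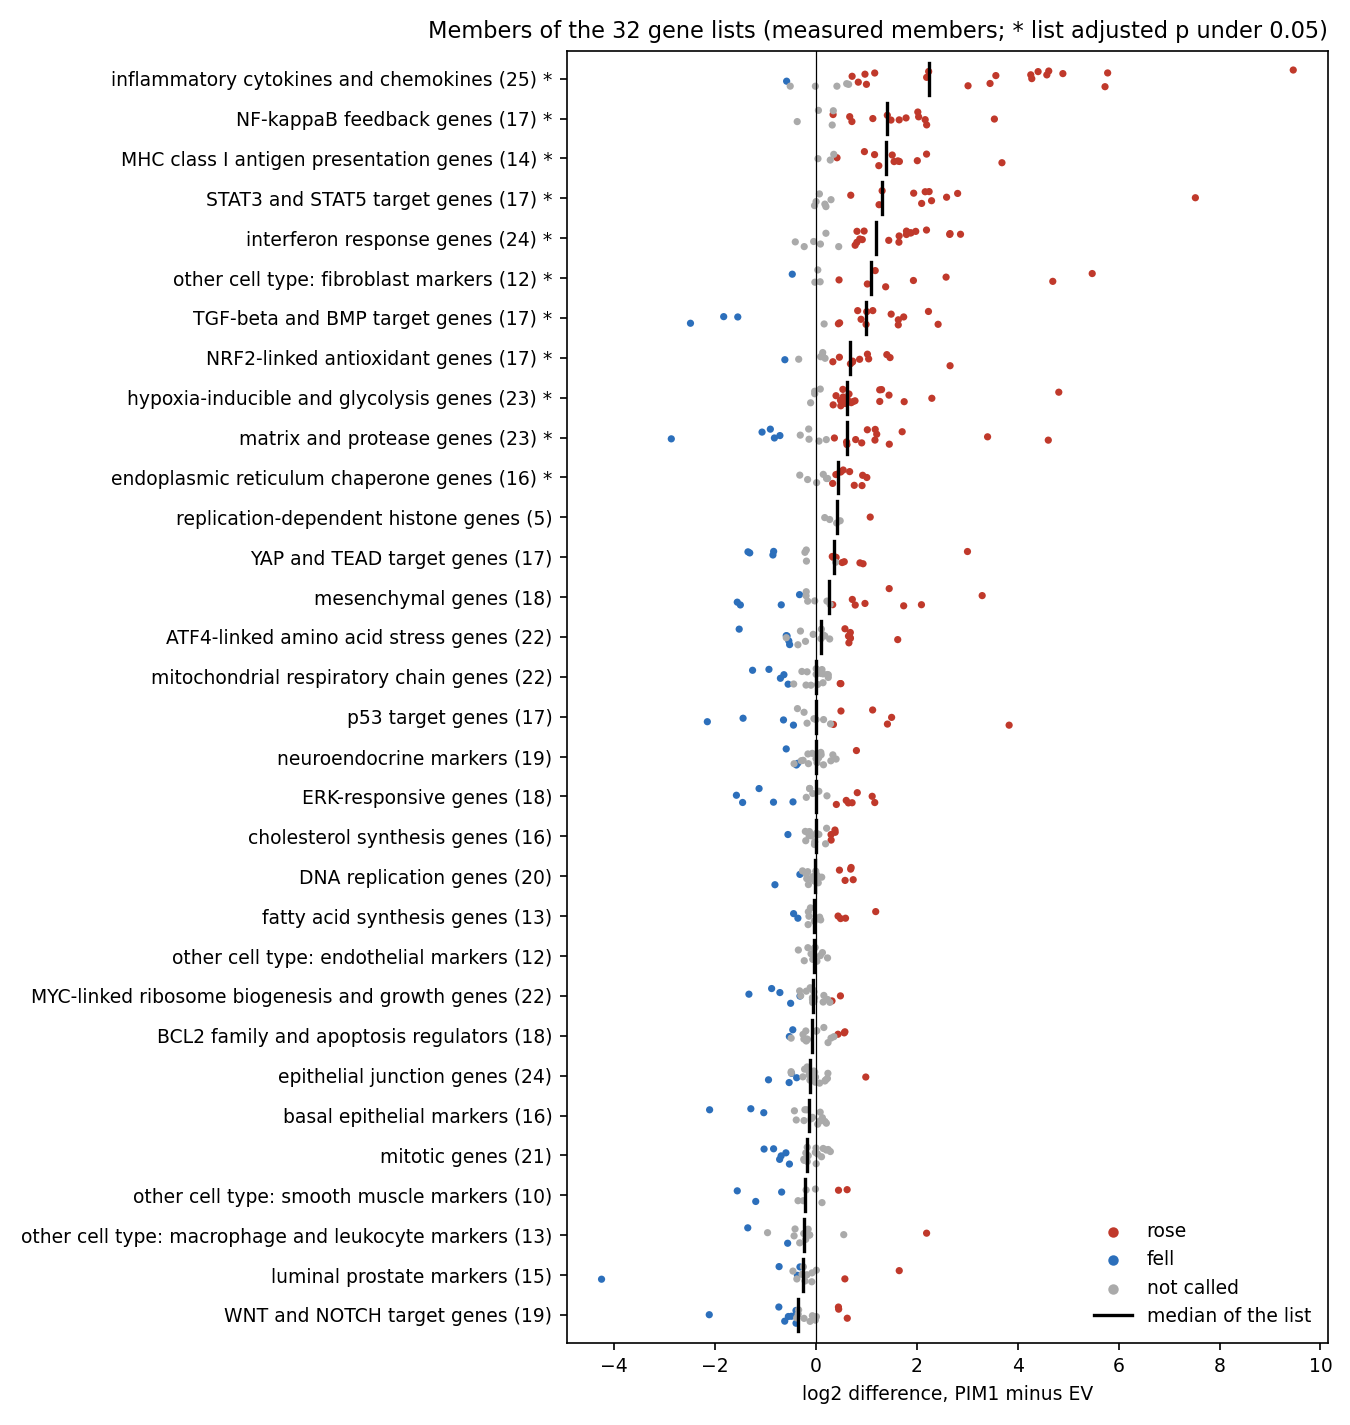
Log2 difference (PIM1 minus EV, x axis) of each measured member of the 32 gene lists (y axis, with the number of measured members), 1 point per gene; red points rose, blue points fell, grey points were not called, black bars are list medians and an asterisk marks a list with camera adjusted p under 0.05. The list of inflammatory cytokines and chemokines has the highest median, 2.24, and WNT and NOTCH target genes the lowest, -0.35.

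The camera test called 11 of the 32 lists, all of them higher in PIM1. With an estimated correlation 5 calls held, those of inflammatory cytokines and chemokines (adjusted p = 0.0220), hypoxia-inducible and glycolysis genes (0.0232), STAT3 and STAT5 target genes (0.0232), MHC class I antigen presentation genes (0.0233) and fibroblast markers (0.0439). The fry test, which asks whether the genes of a list move on balance in 1 direction and compares them with no other gene, called 24 lists, and its mixed form, which counts changes in either direction, called 31. Endothelial markers were the list that the mixed form did not call (adjusted p = 0.490). The sign of the median differed from that of the camera test for DNA replication, respiratory chain, cholesterol synthesis, fatty acid synthesis, neuroendocrine and BCL2 family lists, the largest of these medians in size being -0.08 for the BCL2 list. The mean of the BCL2 list (-0.00014) and that of the ERK list (-0.0083) also had the opposite sign to their camera tests, while the fry direction of the ERK list was down.

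**Figure D3:**
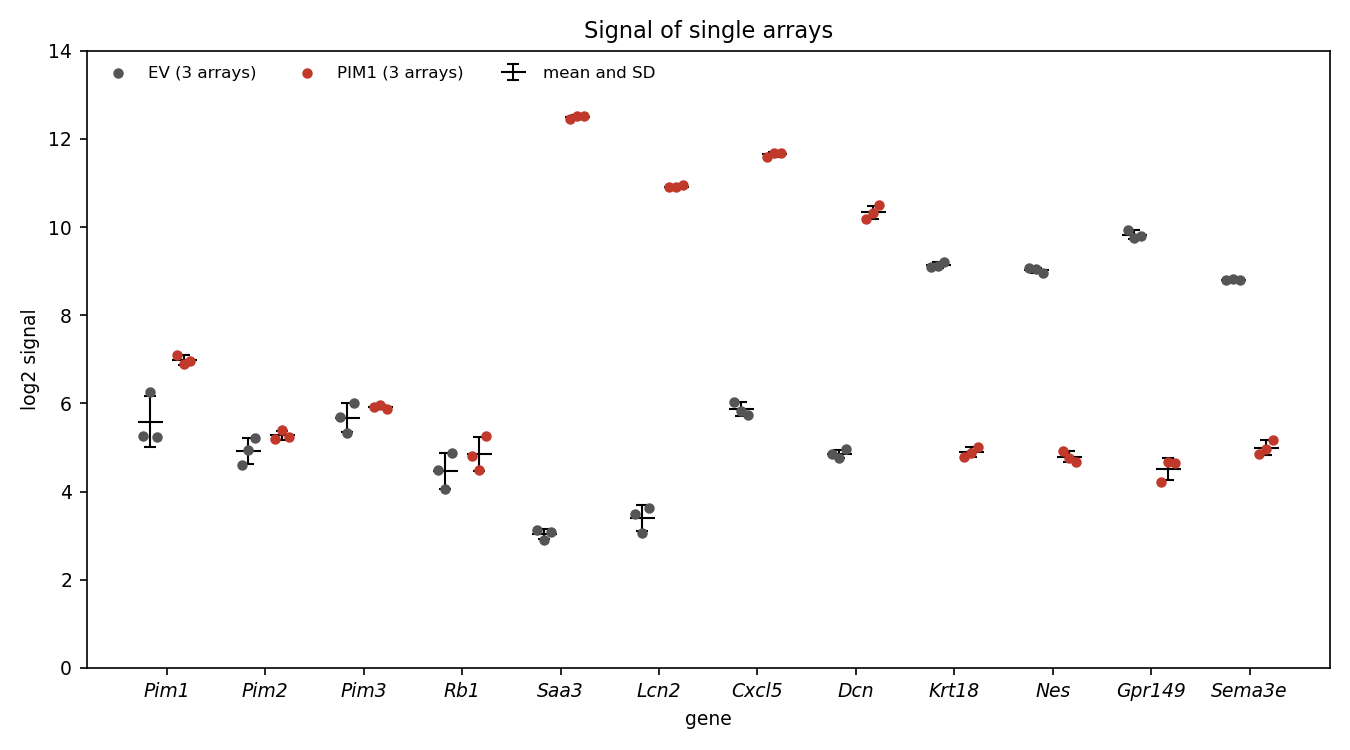
Log2 signal (y axis) of 12 genes (x axis) on each of the 3 EV arrays in grey and the 3 PIM1 arrays in red; dashes are group means and bars are SDs. Saa3 lay between 2.90 and 3.13 on the EV arrays and between 12.46 and 12.53 on the PIM1 arrays, whereas the Pim2, Pim3 and Rb1 arrays of the groups overlapped.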

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

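No explanation was tested in this part, and the counts use the same limma model and thresholds as the named genes. The probe sets counted here lie outside the comparisons of genes. Among 16010 probe sets with no gene symbol, 252 were at least 2-fold higher in PIM1 than in EV cells by limma with adjusted p under 0.05 over all probe sets. The largest of these differences was 8.86 on the log2 scale, from a mean of 2.99 in EV. In the same class 465 were at least 2-fold lower, and without a size limit 598 were higher and 1162 lower. Among 1814 probe sets with several gene symbols, 64 were at least 2-fold higher and 38 at least 2-fold lower. These probe sets were not assigned to genes here.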

How the results depend on the processing

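Cyclic loess and the 2-fold count over all probe sets were the alternatives chosen only after the data were seen. The count of changed genes, 5995, was between 5321 and 6574 over the other variance, normalizations, filter, averaged probe sets and the block, and between 4167 and 5369 when 1 array was left out. The 2-fold count was 1257 to 1525 over the same settings, and 1355 to 1446 with 1 array left out. Over all 41345 probe sets, with or without a gene symbol, 6748 probe sets were called and 2319 at 2-fold, where more features were tested. Of the genes called, 80.9% were still called in the same direction after quantile normalization, 84.0% after cyclic loess, 85.6% after median centring and 68.3% without PIM1 replicate 2, where fewer arrays were tested; 1 gene was called in the opposite direction when probe sets were averaged, and 0 under the others. The 11 called lists were still called under every normalization, variance and left-out array, with 11 to 13 lists called when 1 array was left out. Matrix and protease genes were lost among the brighter 11090 genes. Lists called were 5 with an estimated correlation and 24 with fry (16 higher and 8 lower), since fry asks another question. Quantile normalization and cyclic loess called 14 lists, adding mitotic, MYC-linked and WNT and NOTCH genes as lower, and the cause was not tested. The brighter genes alone added mitotic genes, epithelial junction genes and basal epithelial markers as lower (adjusted p = 0.0202, 0.0213 and 0.0270), and leaving out EV replicate 2 also added basal markers (0.0320). The junction and basal calls among the brighter genes rest on few members. Medians of 11 uncalled lists changed sign under some alternative, to at most 0.102 in size. Of 149 named genes 130 kept their call under every one of the 13 alternatives in which they were tested, and 0 changed sign. Dim named genes were not tested among the brighter 11090 genes. Tnf, Taldo1, Inhba, Skil and Fap are not among the 149, and Tnf and Fap lost their calls under some alternatives. Rrm2, among the DNA replication genes, fell from a difference of 0.70 to 0.21 (adjusted p = 0.141) when its probe sets were averaged. With the replicate number as a block, 5321 genes, 1390 at 2-fold and 12 lists were called, and Rb1 (adjusted p = 0.0472) and the WNT and NOTCH list (0.0472) passed. Deviations of same-numbered arrays correlated at 0.056, -0.031 and 0.0088, so these arrays shared no clear deviation over all genes. A pairing without such a shared deviation is not excluded, and the labels do not state one. Dim genes hold an unknown share of background. The median difference was -0.13 for genes with a mean under 3 and 0.18 for genes between 5 and 6, and the cause of this pattern was not tested.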

Other observations

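The gene families in the first 2 paragraphs and the tests of other cell types, of unequal spread, of chance placement along chromosomes and of unequal chromosome copies were chosen only after the results were seen. For these families counts and medians are given, and no family test is reported. Of 22 acute-phase protein genes measured, the already described Saa3 and Lbp among them, 12 rose and 1 fell, with a median difference of 1.22. Ceruloplasmin (Cp) rose by 5.00, the protease inhibitor gene Serpina3n by 4.51, the orosomucoid gene Orm2 by 4.15 and haptoglobin (Hp) by 3.95. Of 22 complement component and regulator genes, 9 rose, 0 fell and 13 were not called (median 0.30). Factor B (Cfb) rose by 5.15, C4b by 4.11 and the inhibitor gene Serping1 by 2.30. Among 13 interferon-inducible GTPase genes, which act against intracellular pathogens, 9 rose and 0 fell (median 1.57). Iigp1 rose by 4.51, Gbp9 by 3.93 and Gbp7 by 3.59. Of 12 Toll-like receptor genes 4 rose, Tlr2 by 3.04, and 0 fell (median 0.09). In the same PIM1 arrays 8 of 12 fibroblast markers rose, with a median difference of 1.10 (camera adjusted p = 5.25e-06). The medians of these 4 families had the same sign under quantile normalization, median centring and cyclic loess.

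Of 10 Hoxb genes, which help to specify position along the body axis, 5 fell and 1 rose in PIM1 cells (median -0.34). Hoxb9 fell by 1.43, Hoxb3 by 1.01 and Hoxb6 by 0.85, whereas Hoxb13, a prostate lineage gene, rose by 0.58. The Hoxb median was negative under each of the 3 scalings, between -0.25 and -0.48. Hoxd9 and Hoxd8 rose by 1.50 and 0.90, and Hoxa13 by 0.94. Most genes of the other clusters were not called. Of 9 Hoxa genes 2 rose and 0 fell (median 0.18), and of 8 Hoxd genes 2 rose and 0 fell (median -0.10). Among 9 Hoxc genes 0 rose and 0 fell (median -0.25). The fibroblast marker median of 1.10 applies to these arrays as well. Of 20 semaphorin genes 4 rose and 6 fell. Sema7a fell by 2.44 and Sema3a fell by 2.05, whereas Sema3f rose by 0.87. Of 13 Eph receptor genes 3 rose and 5 fell (median -0.16). Epha4 fell by 2.26 and Epha7 fell by 1.38, whereas Ephb6 rose by 1.37. Of 8 ephrin genes 3 rose and 3 fell (median 0.16). The semaphorin median changed sign after median centring, from -0.09 to 0.01.

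Krt18 fell by 4.24 (95% interval -4.48 to -4.01) while fibroblast markers rose in the PIM1 arrays. Replacement of epithelial cells by another cell type would lower other epithelial markers as much, which stays open: the 9 others with an EV mean of at least 5 had a median of -0.48 (95% bootstrap interval -1.29 to -0.07), 6 falling, Cd24a rising by 1.65 and Foxa1 and Sfn differing by -0.21 and -0.07 without a call, but Tjp1 (-0.53) and Itga6 (-2.10) alone started 4.24 or more above the median signal of the PIM1 arrays (median -1.32), and 2 markers are too few to decide. The other measured junction, basal and luminal markers, Krt8 and Epcam among them, lay below 5 in EV already. Most epithelial markers were thus dim in the EV cells. Fibroblasts added to the PIM1 cultures also cannot be told apart from a change in the cells themselves. Of 12 markers 8 rose, 2 of which the matrix list also holds, all 6 with an EV mean of at least 5 rose, and Col3a1 and Col1a1 were already at 9.96 and 8.94 in EV, while Lum (1.78 to 2.24) and Thy1 (3.75 to 3.73) stayed low and the fall of Fap lay at a low signal. PIM1 itself may have changed these genes, which the design cannot separate from a difference between the transduced populations.

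The large number of changed genes goes with a wider spread of values on the PIM1 arrays. If the difference in spread between arrays were the whole cause, quantile normalization should remove most calls, but 80.87% of the called genes were still called in the same direction. After cyclic loess, which removes a brightness-dependent difference between arrays, 83.97% were. The share of higher calls moved with the scaling, so the balance of rises and falls stays open, and a biological difference between the groups was not tested apart from the scaling. There are too few splits of the 6 arrays for a share under 0.05, since 1 of 10 is the smallest: the real split called 5995 genes, 1388 at 2-fold and 11 lists, and the highest of the others 0, 0 and 10. The other splits mix the groups, which widens the spread within each side and keeps part of the real difference. Their counts are thus not those of arrays without a difference.

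Genes of some chromosomes shifted together between the groups: among 8862 genes with a mean of at least 5, chromosome medians spread with an SD of 0.113 on the log2 scale, where chromosome 12 lay 0.18 above the median of all these genes and chromosome 13 lay at -0.19, although no chromosome passed alone (lowest adjusted p = 0.230). Chance placement of the changed genes gave as large a spread in a share of 0.0020 of 10000 rotations of the gene order, whose median spread was 0.0882 (0.0284 over 1000 shuffles of single genes, which do not keep neighbours together), and a share of 0.0013 gave it after a brightness-dependent difference was removed, so these 2 explanations are argued against. Arrays of the same group differed by an SD of at most 0.041 and those of different groups by at least 0.109. The criterion set beforehand compared the 0.041 with the whole spread between the groups, 0.113. By that criterion the values argue against differences between single arrays. However, the groups differ in many more genes, and the rotations alone gave 0.0882. Against the spread beyond the rotations, 0.070, a comparison not set beforehand, the 0.041 does not exclude differences between single arrays. As a hypothesis, the populations may carry unequal chromosome copies: medians of the first and last part of each of the 20 chromosomes correlated at r = 0.755 (permutation p = 1.2e-04). Spearman's rho was 0.705 (permutation p = 6.6e-04). Without chromosomes 7 and 12, whose first parts lay farthest from the median of the first parts, r was 0.772. The correlation was sought after the spread of chromosome medians was seen. Any shift shared along a chromosome would give it, so it does not single out unequal copies. The GC content of the probes was not tested and stays open, as does an effect of PIM1 on neighbouring genes.

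The Y-linked genes Kdm5d, Uty and Eif2s3y rose by 1.09, 0.91 and 0.72 in PIM1 (adjusted p = 0.00133, 0.0203 and 0.0219). Their median of 0.91 lay at percentile 95.5 of 10000 random lists of 3 genes with similar signal. This percentile is one-sided. The random genes were drawn singly and not as neighbours on 1 chromosome, so the reference may be too narrow and decides nothing. Ddx3y, also sought, was not among the genes tested, and these genes were in no list or naming rule fixed beforehand.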
